A study of Mus musculus with 9 samples.

How the data were processed

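One deposited table held the FPKM of 35321 genes in 9 samples, with gene symbols and annotation columns. Per the submitters' processing notes, fastp 0.22.0 and HISAT2 2.2.1 were used and the genome build was named GRCh38. That is a human build, while the symbols and descriptions in the table are those of mouse genes, so no coordinates are printed. The read counter and the annotation are not given in the sources used here. Per the labels, libraries were poly(A)-selected and sequenced as 150 bp read pairs on an Illumina NovaSeq instrument. Each column held 1 sample, and 3 samples made up each of the groups vehicle, digoxin at 0.1 mg/kg and digoxin at 1 mg/kg.

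The depth of each library was recovered from the spacing of its FPKM values, which are whole reads divided by gene length and depth. With these depths and a whole length fitted to each gene, 99.96% of the genes and 99.95% of the tested genes gave whole reads in every sample within 0.03 reads. A fitting length is easily found for genes read in few samples, so the figure for all genes is a weak check. The recovered depths were 48649867, 50033250 and 51810956 with vehicle, 42870997, 42940131 and 43319883 at 0.1 mg/kg, and 42252370, 40571927 and 40517062 at 1 mg/kg. One read was thus worth up to 1.20 times as much FPKM as in vehicle sample 1. These depths are denominators of the FPKM values, with 99.57% to 99.76% recovered in genes, and are not counts of all sequenced reads. Whether 1 read here stands for a read or a read pair is not stated. The recovered reads served for the thinning test and a limma-voom alternative only.

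The FPKM values as deposited were transformed to log2(FPKM + 1), and genes with at least 1 FPKM in at least 3 of the 9 samples were tested (13687). The test was limma 3.58.1 in R 4.3.3: 1 mean per group, 1 fit of all 9 samples, no replicate block, moderated two-sided t-tests with a mean-variance trend, and Benjamini-Hochberg adjustment over all tested genes with a threshold of 0.05. The residual degrees of freedom were 6 and the prior degrees of freedom 2.71. The 3 contrasts were each dose against vehicle and 1 mg/kg against 0.1 mg/kg. Means are given ± SD and fold changes with standard errors. The deposited unit was FPKM, and limma-voom on reads recovered from it was run only as an alternative.

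Of 45 gene lists fixed before the data were examined, the 42 with at least 5 tested members were tested with camera from limma, with a preset correlation of 0.01 between genes, and adjusted over the lists of a comparison. Of the 880 symbols in these lists, 862 were found as written, 10 by a synonym and 8 were not found. Some lists share members, so their calls are not independent. Among them are HIF-1 targets with glycolysis enzymes, inflammatory cytokine genes with chemokines, and heat shock with NFAT5 genes. Members that passed were counted over all genes tested and also adjusted over the list alone. Camera with an estimated correlation, and fry, were alternatives. In the alternative with no expression filter, camera compared each list with all 35321 genes, most of them below the filter. A pass there thus rests on a different background. Genes were named by a rule fixed at the same time. It took the 12 largest rises and the 12 largest falls per comparison among genes with an adjusted p under 0.05 whose replicate values did not overlap. It left out genes without a symbol, predicted or unnamed genes and pseudogenes. If under 5 genes passed in a direction, the 5 with the smallest unadjusted p were given as values. It added up to 4 members with the smallest unadjusted p of each list described, and targeted genes: Atp1b1, Hif1a, Vegfa, Cd274, Pdcd1, Ctla4, Cd8a, Cd4, Foxp3, Ifng, Gzmb and Prf1. Some genes that the rule named are not reported here.

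Agreement between the doses was set beside 100 draws of unchanged groups simulated against the same vehicle libraries. The alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.01, no filter, a mean FPKM of at least 5, quantile normalisation, rescaling to TPM, equal medians, limma without trend, robust empirical Bayes, a fit of only the 2 groups compared, a replicate block, each library left out in turn, and thresholds that included a 2-fold change. Added after seeing the data were leaving out both libraries that lay between the groups, limma-voom, removal of each library's loess trend (span 0.5) on GC content and transcript length, and the count of genes for both doses together. GC content was available for 95.6% of the tested genes. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 was used for the remaining calculations.

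The limma step was tested on simulated data of 13687 genes with 100 genes changed by log2 1 and 100 by log2 2. For 0.1 mg/kg against vehicle it recovered 73% and 93%, with 6.2% of the calls false (11 of 177). For 1 mg/kg against vehicle it recovered 69% and 92%, with 4.7% false (8 of 169), and between the doses 82% and 90%, with 3.4% false (6 of 178). All simulated groups had the same spread for a gene. In the data, correlations between libraries were 0.99 to 0.994 with vehicle, 0.962 to 0.984 at 0.1 mg/kg and 0.953 to 0.99 at 1 mg/kg. These rates of false calls thus may not hold where the groups differ in spread. With every T cell marker raised in simulated data for 0.1 mg/kg against vehicle, camera called that list (adjusted p = 9.52e-23) and 0 of the others. Simulated genes varied independently, whereas the estimated correlation of T cell markers in the data was 0.66. The simulation therefore cannot show how often camera with the preset correlation calls correlated lists falsely.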

Results

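Poly(A) RNA was sequenced in 9 samples of subcutaneous tumours grown from LLC cells, the Lewis lung carcinoma line of C57BL/6 mice. Per the labels, the cells were injected into the right flank of male C57BL/6 mice aged 4 to 5 weeks, and intraperitoneal treatment began 5 days later. The 3 groups of 3 samples received vehicle (PBS), digoxin at 0.1 mg/kg or digoxin at 1 mg/kg. Digoxin is a cardiac glycoside that inhibits the Na,K-ATPase, the membrane pump that exports sodium and imports potassium. The deposited values were FPKM. The depth in their denominator was recovered from their spacing. It was 48649867 to 51810956 in the vehicle libraries, 42870997 to 43319883 at 0.1 mg/kg and 40517062 to 42252370 at 1 mg/kg. Of the 35321 genes in the table, 13687 reached 1 FPKM in at least 3 of the 9 libraries and were tested. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. The labels do not say that the samples of a group came from separate mice, so p-values measure only the spread between these samples, which may be technical.

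The first principal component, with 69.4% of the variance, separated the vehicle libraries from the digoxin libraries. Vehicle samples scored −47.6 to −55.0, and 4 of the 6 digoxin samples scored 35.7 to 37.9. The remaining pair lay between the groups: sample 2 of the 0.1 mg/kg group scored −0.6 and sample 1 of the 1 mg/kg group scored 9.12. On the second component (12.4%), sample 1 of the 1 mg/kg group scored −43.95 and every other library scored between −1.17 and 19.1. Pearson correlations of log2 values across genes, which are not independent replicates, were 0.99 to 0.994 among vehicle libraries, 0.962 to 0.984 within the 0.1 mg/kg group and 0.953 to 0.99 within the 1 mg/kg group. Between vehicle and digoxin libraries they were 0.884 to 0.958.

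**Figure D1:**
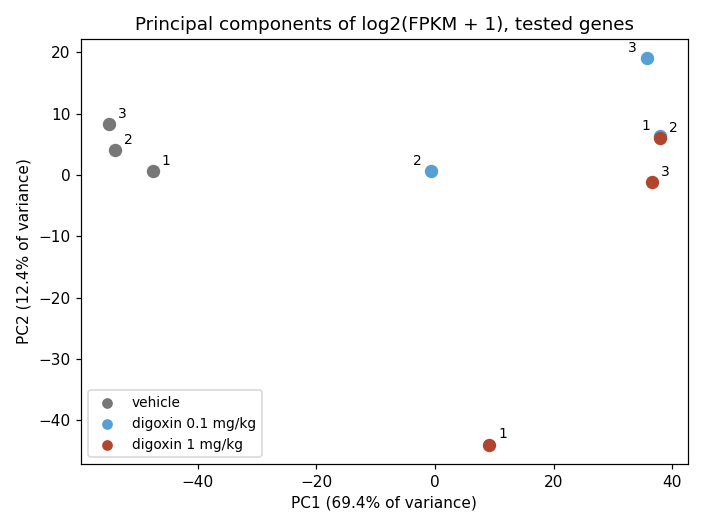
First and second principal components of log2(FPKM + 1) over the 13687 tested genes, 1 point per library, labelled with the sample number and coloured by group. Vehicle libraries lie at −47.6 to −55.0 on the first component, and 2 digoxin libraries lie apart from the other 4, at −0.6 and 9.12.

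The comparison of 0.1 mg/kg digoxin with vehicle asked which transcripts of the tumour tissue differed at the lower dose. Camera with a preset correlation called the interferon, antigen-processing, T cell and cytotoxic lists higher and the DNA replication list lower. Each of these calls was lost with an estimated correlation (adjusted p = 0.595, 0 of 42 lists called). Fry passed 23 of 42 lists (20 higher, 3 lower), these among them, but it does not compare a list with other genes. In all, 5781 of 13687 genes passed an adjusted p of 0.05 in limma, of which 2952 were higher and 2829 lower, and 1222 of them differed at least 2-fold (901 higher, 321 lower). The 3 digoxin and 3 vehicle values did not overlap for 60.2% of the tested genes, against 10% by chance. With quantile normalisation the same comparison gave 2403 higher and 3552 lower genes, and with rescaling to TPM 2368 and 3790. The count was 3492 without vehicle sample 2, 3482 without vehicle sample 3, 3739 without 0.1 mg/kg sample 1 and 3414 without 0.1 mg/kg sample 3. It was 8424 without both libraries that lay between the groups, a setting chosen after seeing the data.

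The largest rise at 0.1 mg/kg was that of Prl2c3, a proliferin-family hormone gene, from 2.27 ± 1.22 to 146 ± 92.1 FPKM (SD, n = 3; log2 fold change 5.28, SE 0.66). Its near-identical relative Prl2c2 rose by 3.74 on the log2 scale, and how reads were shared between the 2 genes is uncertain. Krt8, which encodes a keratin of simple epithelia, went from 2.76 ± 1.24 to 85.6 ± 24.1 FPKM (log2 4.54, SE 0.26, limma adjusted p = 0.000101). Slc47a1 (an organic cation and drug exporter, log2 4.65), Tm9sf5 (4.32), Lgals7 (a galectin, 4.19), Fosb (an AP-1 transcription factor subunit, 4.12), Syt8 (4.10), Efemp1 (a fibulin of the extracellular matrix, 4.01), Sncg (gamma-synuclein, 4.01) and Acap1 (3.97) completed the largest rises that held when any 1 library was left out. Myh6, a cardiac myosin heavy chain, was 4.74 higher, but its call was lost in 3 of the 9 fits that left out 1 library (highest limma adjusted p = 0.074, without 0.1 mg/kg sample 3).

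Krt18, the usual keratin partner of Krt8, fell by 3.64 on the log2 scale (SE 0.86), from 55.7 ± 10.9 to 6.46 ± 8.99 FPKM. Its FPKM was 16.8 in 0.1 mg/kg sample 2, against 1.62 and 0.932 in the other samples of that group. Fads2, a fatty acid desaturase, fell by 2.89, and so did Bnc1 and Wnt7b, a Wnt ligand. Stra6 (a retinol uptake receptor, log2 −2.92), Esx1 (a homeobox gene, −2.80) and Lgi2 (−2.80) also fell. Of the 12 largest falls, 4 lost their limma call without 0.1 mg/kg sample 3: Nptx1 (log2 −3.94, adjusted p = 0.0528), Cpe (−3.37, 0.0526), Ntn1 (−3.33, 0.138) and Scara3 (−2.98, 0.159). For Ntn1 and Scara3, 5 and 6 other single libraries ended the call too.

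Among the genes of the pump that digoxin inhibits, the beta-1 subunit Atp1b1 rose from 0.782 ± 0.132 to 4.60 ± 1.29 FPKM (log2 1.63), and the regulator Fxyd5 rose by 0.59. Of the 9 tested Na,K-ATPase and FXYD genes, 3 rose and 1 fell (4 and 1 adjusted over the list alone), with a camera adjusted p = 0.0447. That call was lost with an estimated correlation (adjusted p = 0.595), with quantile normalisation (0.0551) and without 0.1 mg/kg sample 1 (0.0579) or sample 3 (0.0605).

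All 29 tested type I interferon response genes rose at 0.1 mg/kg (29 adjusted over the list alone, median log2 1.96, camera adjusted p = 1.75e-14, and adjusted p = 0.595 with an estimated correlation). Isg15, a ubiquitin-like modifier, went from 16.9 ± 2.72 to 193 ± 34.8 FPKM (log2 3.43, SE 0.31). The antiviral effectors Mx1 (log2 2.86) and Oas2 (2.5) and the nucleotide kinase Cmpk2 (2.07) rose with it. Of 22 interferon-gamma response genes, 20 rose (20 adjusted over the list alone, median 2.2, camera adjusted p = 8.78e-12), among them the immunity-related GTPases Igtp (2.96), Irgm2 (2.62) and Tgtp1 (2.42) and the interferon-inducible Ifi47 (2.83). Of 19 genes of MHC class I and antigen processing, 16 rose (16 adjusted over the list alone, median 1.64, camera adjusted p = 8.05e-10). The immunoproteasome subunit Psmb8 went from 6.27 ± 1.14 to 75.2 ± 25.8 FPKM (log2 3.34), and the peptide transporter Tap1 rose by 2.32. The class I genes H2-T23 (2.02) and H2-T22 (1.87) also rose, with the reservation that reads of related H2 genes can be hard to separate. Both of these calls had an adjusted p = 0.595 with an estimated correlation.

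Of 15 T cell markers, 12 rose and none fell (13 and 0 adjusted over the list alone, median log2 0.93, camera adjusted p = 0.000899, and adjusted p = 0.595 with an estimated correlation). Trbc1, a T cell receptor constant region, rose from 3.76 ± 0.249 to 16.8 ± 3.95 FPKM (log2 1.87, SE 0.33), with Lat (1.44) and Cd28 (1.10), both of T cell receptor signalling. Cd8a was 1.77 ± 0.165 and 3.92 ± 1.05 FPKM (log2 0.80, limma adjusted p = 0.023), and its call was lost in 5 of the 9 fits that left out 1 library (highest adjusted p = 0.0839, without 0.1 mg/kg sample 3). Cd4 was 1.36 ± 0.282 and 1.43 ± 0.375 FPKM (log2 0.03, limma adjusted p = 0.913). Of 12 cytotoxic and NK effector genes, 9 rose (10 adjusted over the list alone, median 1.03, camera adjusted p = 0.00491, and 0.112 among genes with a mean of at least 5 FPKM). With an estimated correlation this list had an adjusted p = 0.595. Gzmb, the protease granzyme B, rose from 5.56 ± 0.91 to 24.2 ± 5.64 FPKM (log2 1.92, SE 0.31). The pore-forming Prf1 rose from 1.11 ± 0.181 to 6.24 ± 0.623 FPKM (log2 1.78), and the transcription factor Eomes by 1.05.

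Of 19 immune checkpoint genes, 14 rose and 1 fell (14 and 1 adjusted over the list alone, median log2 0.76, camera adjusted p = 0.000241, and adjusted p = 0.595 with an estimated correlation). Cd274, which encodes PD-L1, rose from 3.51 ± 0.208 to 18.3 ± 8.25 FPKM (log2 2.01, SE 0.39, limma adjusted p = 0.00516). The receptors Pdcd1 (log2 1.83, limma adjusted p = 0.004), Ctla4 (1.08), Lag3 (1.41), Havcr2 (1.38) and Tigit (1.26) rose, as did Cd47 (0.76), a signal against phagocytosis. Foxp3 and Ifng did not reach the expression filter. Foxp3 was at 0.0667 ± 0.0240 FPKM with vehicle, 0.188 ± 0.0719 at 0.1 mg/kg and 0.110 ± 0.0269 at 1 mg/kg, and Ifng at 0.160 ± 0.0547, 0.974 ± 0.333 and 0.170 ± 0.0705 FPKM.

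At 0.1 mg/kg, of 20 inflammatory macrophage and cytokine genes, 12 rose (12 adjusted over the list alone, median log2 0.91, camera adjusted p = 5e-04), including Nos2 (inducible nitric oxide synthase, 2.38), Ccl4 (2.2), Ccl3 (2.12) and Il18 (1.73). Of 20 neutrophil and granulocytic genes, 10 rose (10 adjusted over the list alone, median 1.19, camera adjusted p = 0.00104), with Padi4, a histone-citrullinating enzyme, going from 0.978 ± 0.319 to 14.8 ± 1.90 FPKM (log2 3.0, SE 0.18). Of 20 macrophage markers, 9 rose and 1 fell (11 and 1 adjusted over the list alone, median 0.67, camera adjusted p = 0.00482). Fcer1g rose by 1.19, and Cx3cr1, the fractalkine receptor, fell by 2.13. Of 24 chemokines, 14 rose and 2 fell (14 and 3 adjusted over the list alone, camera adjusted p = 0.00385), with Ccl8 at 55.2 ± 36.4 and 599 ± 262 FPKM (log2 3.48) and Cxcl10 2.14 higher. Complement genes rose in 9 cases of 14 and fell in 1 (13 and 1 adjusted over the list alone, camera adjusted p = 0.000825), led by C1s1 (1.95) and C3 (1.61). MHC class II presentation genes rose in 5 cases of 10 (5 adjusted over the list alone, median 0.95, camera adjusted p = 0.00999), with Ctss 1.13 higher. All 6 of these calls had an adjusted p = 0.595 with an estimated correlation.

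At 0.1 mg/kg, of 23 genes of the unfolded protein and integrated stress response, 14 rose and 2 fell (16 and 2 adjusted over the list alone, median log2 0.51, camera adjusted p = 0.00104), including Chac1 (2.01), Trib3 (1.37) and Ddit3, the transcription factor CHOP (1.19). Of 23 immediate early genes, 13 rose and 2 fell (16 and 3 adjusted over the list alone, median 0.76, camera adjusted p = 0.00491). Fos rose by 2.88 and Jund by 0.89, and Egr3 fell by 0.78. Of 30 DNA replication and E2F target genes, 15 fell and 3 rose (16 and 3 adjusted over the list alone, median −0.31, camera adjusted p = 0.0018), including Pola1 (−0.68), Chaf1a (−0.63), Cdc6 (−0.49) and Rrm1 (−0.38). With an estimated correlation the adjusted p = 0.672 for immediate early genes and 0.595 for the other lists of this paragraph. HIF-1 target genes rose in 3 cases of 28 and fell in 2 (1 and 0 adjusted over the list alone, camera adjusted p = 0.861), with the collagen hydroxylase P4ha2 1.83 higher. Hif1a itself was at 38.2 ± 3.28 and 28.1 ± 4.08 FPKM (log2 −0.44, limma adjusted p = 0.0285), a call lost in 3 of the 9 fits that left out 1 library (highest adjusted p = 0.1, without 0.1 mg/kg sample 3). Vegfa was at 14.0 ± 0.668 and 16.8 ± 6.52 FPKM (log2 0.18, limma adjusted p = 0.725).

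Markers of other tissues also differed. Of 14 skeletal muscle markers, 7 rose at 0.1 mg/kg and 7 at 1 mg/kg (8 at each dose adjusted over the list alone, medians log2 1.99 and 2.25, camera adjusted p = 0.00482 and 0.00147). Both calls were lost with an estimated correlation (adjusted p = 0.666 and 0.699). The muscle enolase Eno3 was at 19.2 ± 1.66 FPKM with vehicle, 49.0 ± 8.53 at 0.1 mg/kg and 70.9 ± 28.8 at 1 mg/kg. The troponin gene Tnnt3 ranged from 2.82 to 7.47 FPKM in the vehicle libraries, from 21.7 to 44.4 at 0.1 mg/kg and from 7.79 to 195 at 1 mg/kg. Its calls were lost in 7 and 4 of the 9 fits that left out 1 library (highest limma adjusted p = 0.124 without 0.1 mg/kg sample 3, and 0.069 without vehicle sample 3). Of 22 endothelial markers, 1 fell at 0.1 mg/kg and none changed at 1 mg/kg (0 at either dose adjusted over the list alone, camera adjusted p = 0.939 and 0.601). The gene that fell was Apln, a ligand of endothelial tip cells (−0.93). Without 1 mg/kg sample 1 the endothelial list was higher at 1 mg/kg (median 0.45, camera adjusted p = 0.00569, and 0.00621 without both libraries that lay between the groups). Of 26 fibroblast and collagen matrix genes, 12 fell and 6 rose at 0.1 mg/kg, and 14 fell and 4 rose at 1 mg/kg (15 and 6, then 14 and 5, adjusted over the list alone, camera adjusted p = 0.158 and 0.121). The collagen cross-linking enzyme Loxl2 fell by 2.15 and 2.39 at the 2 doses, Col5a2 fell by 1.94 and 2.12, and the matrix protein Fbln1 rose by 1.34 and 1.46. This list passed at 0.1 mg/kg with no filter (0.0199) and in fry (0.0287), and at 1 mg/kg under both of these (0.00528 and 0.00782), without 1 mg/kg sample 1 (0.0338) and without both libraries that lay between the groups (0.0224).

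**Figure D2:**
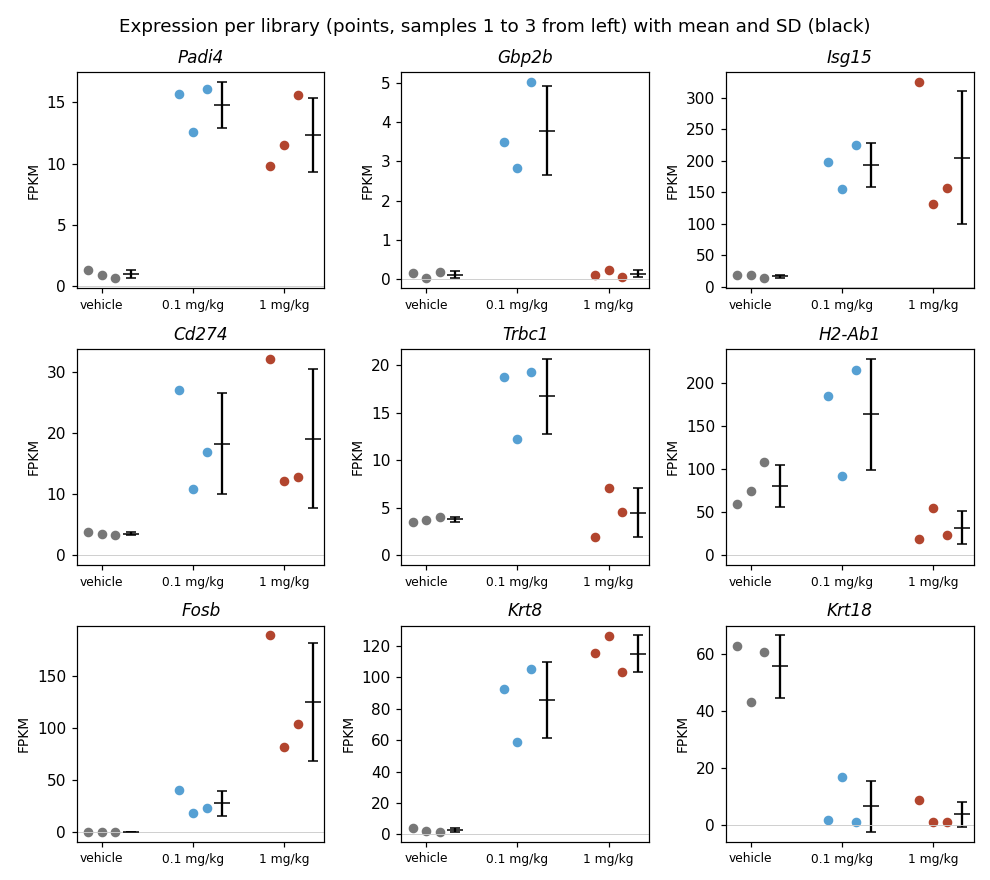
FPKM of 9 genes in each library (points, samples 1 to 3 from left), with the group mean and SD (black), n = 3 per group, on linear axes from near 0. Isg15 and Cd274 are higher at both doses, Trbc1 averages 3.76, 16.8 and 4.48 FPKM, and Krt18 keeps 16.8 FPKM in 0.1 mg/kg sample 2 and 8.84 in 1 mg/kg sample 1.

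The comparison of 1 mg/kg digoxin with vehicle asked the same at the higher dose. Camera with a preset correlation called the interferon, antigen-processing, immediate early, inflammatory cytokine and neutrophil lists higher and the DNA replication list lower, and gave no call for T cell markers. Each of these calls was lost with an estimated correlation (adjusted p = 0.655, 0 of 42 lists called). Fry passed 16 of 42 lists (14 higher, 2 lower), the called lists named here among them. In limma, 6277 of 13687 genes passed, 2833 higher and 3444 lower, and 1369 of them differed at least 2-fold (913 higher, 456 lower). The values did not overlap between the groups for 58.3% of genes, against 10% by chance. The balance of directions depended on 1 mg/kg sample 1, without which 3849 genes were higher and 3524 lower. The count was 4129 without vehicle sample 3, and 8392 (4298 higher, 4094 lower) without both libraries that lay between the groups, a setting chosen after seeing the data.

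Fosb showed the largest rise at 1 mg/kg, from 0.575 ± 0.0982 to 125 ± 56.4 FPKM (log2 6.23, SE 0.33, limma adjusted p = 5.6e-05). Krt8 reached 115 ± 11.6 FPKM (log2 5.00, SE 0.26), and Fos rose from 10.4 ± 2.86 to 319 ± 137 FPKM (log2 4.76, SE 0.41). The further large rises were those of Tm9sf5 (4.90), Syt8 (4.64), Acap1 (4.64), the neutrophil chemokine Cxcl2 (4.42), the plasminogen activator inhibitor Serpinb2 (4.30), Efemp1 (4.18), the MAP kinase phosphatase Dusp1 (4.17), Prl2c3 (4.10) and Magea8, a melanoma antigen family member (4.07). The largest falls were those of Nptx1 (a neuronal pentraxin, −4.18, SE 0.97), Krt18 (−4.02, SE 0.86), Mmp3 (a matrix metalloproteinase, −3.68, SE 0.88), Cx3cr1 (−3.28), Cpe (−3.21), Bnc1 (−3.13), Wnt7b (−3.10), Stra6 (−3.09) and Lgi2 (−3.04). Ntn1 (−3.70), Scara3 (−3.47) and Gpr153 (−3.17) each lost their limma call in 5 of the 9 fits that left out 1 library. Their highest adjusted p were 0.0856 and 0.0839 without 1 mg/kg sample 3 and 0.131 without 1 mg/kg sample 2. Krt18 was at 8.84 FPKM in 1 mg/kg sample 1, against 1.06 and 1.03 in the other samples of that group, and Nptx1 at 8.95, against 0.472 and 0.804.

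At the higher dose Atp1b1 was at 5.97 ± 1.14 FPKM (log2 1.96). Of the 9 Na,K-ATPase and FXYD genes, 4 rose and 1 fell (4 and 1 adjusted over the list alone), with a camera adjusted p = 0.0504. It passed under 10 alternatives, among them leaving out vehicle sample 1 (0.0437) or any 1 of 1 mg/kg samples 1 (0.0389), 2 (0.0431) and 3 (0.0469). Among 12 genes of the NFAT5, sodium and osmotic response, 3 rose and 5 fell at 0.1 mg/kg and 4 rose and 5 fell at 1 mg/kg (the same counts adjusted over the list alone, camera adjusted p = 0.339 and 0.846). In fry this list was lower at 0.1 mg/kg (adjusted p = 0.0142). At 1 mg/kg the salt-responsive kinase Sgk1 rose by 2.81 and Hspa1b by 2.25, while Nfat5 itself fell by 0.88 and the cotransporter Slc12a2 by 0.83.

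At 1 mg/kg, 28 of 29 type I interferon genes rose (29 adjusted over the list alone, median log2 1.85, camera adjusted p = 5.49e-14). Isg15 was at 205 ± 105 FPKM (3.42, SE 0.31), Oas2 was 2.37 higher and Mx1 2.35. Of 22 interferon-gamma response genes, 17 rose and 1 fell (18 and 1 adjusted over the list alone, median 1.46, camera adjusted p = 3.21e-07), including Ifi47 (2.36), Igtp (2.21) and Irgm2 (2.07). Of 19 class I and antigen-processing genes, 15 rose (16 adjusted over the list alone, median 1.44, camera adjusted p = 9.64e-08), with Psmb8 3.09 and H2-K1 2.35 higher. Of 19 checkpoint genes, 11 rose and 1 fell (11 and 1 adjusted over the list alone, median 0.49, camera adjusted p = 0.00224). Cd274 was at 19.1 ± 11.4 FPKM (log2 2.02, SE 0.39, limma adjusted p = 0.00431), Tigit rose by 1.44, Havcr2 by 1.41 and Ctla4 by 0.87, and Cd276 fell by 1.24. Pdcd1 was at 0.527 ± 0.254 FPKM with vehicle and 1.26 ± 1.01 at 1 mg/kg (log2 0.47, limma adjusted p = 0.265). Each of these 4 list calls had an adjusted p = 0.655 with an estimated correlation.

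Of 15 T cell markers, 2 rose and 1 fell at 1 mg/kg (2 and 1 adjusted over the list alone, median log2 −0.09, camera adjusted p = 0.8). Lat rose by 1.20. Trbc1 was at 4.48 ± 2.60 FPKM, against 3.76 ± 0.249 with vehicle. Cd8a was at 1.09 ± 0.662 FPKM (log2 −0.45, limma adjusted p = 0.137), and Cd4 at 0.461 ± 0.358 (−0.72, limma adjusted p = 0.0197, and 0.0746 without vehicle sample 2, 1 of 2 libraries that ended the call). Of 12 cytotoxic and NK genes, 4 rose and 1 fell (4 and 1 adjusted over the list alone, median −0.08, mean 0.27, camera adjusted p = 0.565). Eomes rose by 1.33 and Gzmk fell by 0.93. Gzmb was at 12.5 ± 5.30 FPKM (log2 0.96, limma adjusted p = 0.0332) and Prf1 at 3.52 ± 2.05 (0.97, limma adjusted p = 0.0401), and these calls were lost in 5 and 8 of the 9 fits that left out 1 library (highest adjusted p = 0.109 and 0.132, without 1 mg/kg sample 3). Of 10 MHC class II presentation genes, 1 rose and 4 fell (1 and 5 adjusted over the list alone, median −0.55, camera adjusted p = 0.214, 0.0332 with no filter and 0.035 without 1 mg/kg sample 2). H2-Aa was 1.68 lower and H2-Ab1 1.41 lower, and these calls were lost in 4 fits each that left out 1 library (highest limma adjusted p = 0.089 and 0.0996, without vehicle sample 3). Of 20 macrophage markers, 6 rose and 4 fell (6 and 4 adjusted over the list alone, camera adjusted p = 0.702), with Cd14 1.51 higher and Ms4a7 0.82 lower.

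At 1 mg/kg, of 20 inflammatory macrophage and cytokine genes, 19 rose (20 adjusted over the list alone, median log2 2.14, camera adjusted p = 1.03e-07), including Cxcl2, Cxcl3 (3.86), Nos2 (3.42) and Nfkbiz (2.16). Of 20 neutrophil and granulocytic genes, 17 rose (18 adjusted over the list alone, median 1.88, camera adjusted p = 1.42e-06), including the granule genes Ngp (3.33) and Mmp8 (3.10), with Padi4 (2.74) and Ly6g (1.60). Erythroid genes, which mark blood in the tissue, had medians of 1.31 at 0.1 mg/kg and 1.28 at 1 mg/kg without a camera call (adjusted p = 0.175 and 0.209). In samples 1 to 3 the list means on the log2 scale were 4.13, 3.44 and 3.12 for erythroid and 2.39, 1.89 and 1.61 for neutrophil genes with vehicle, 5.74, 3.89 and 4.22 and 4.15, 3.01 and 2.61 at 0.1 mg/kg, and 4.12, 4.58 and 4.8 and 3.59, 3.78 and 4.34 at 1 mg/kg. Of 23 immediate early genes, 18 rose and 1 fell (18 and 1 adjusted over the list alone, median 1.75, camera adjusted p = 3.37e-07), with Ier2 1.93 higher. Of 23 unfolded protein and integrated stress response genes, 18 rose and 1 fell (19 and 1 adjusted over the list alone, median 0.56, camera adjusted p = 3.22e-06). Ppp1r15a, which encodes the phosphatase subunit GADD34, rose by 2.85 and Chac1 by 2.2. Of 30 DNA replication genes, 17 fell and 3 rose (19 and 4 adjusted over the list alone, median −0.29, camera adjusted p = 0.00332), including E2f2 (−0.79), Pola1 (−0.63), Tyms (−0.61) and Rrm1 (−0.46). Each of these 5 calls had an adjusted p = 0.655 with an estimated correlation.

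Among 28 HIF-1 target genes, 12 rose at 1 mg/kg (12 adjusted over the list alone, median log2 0.60, camera adjusted p = 0.000616, and adjusted p = 0.699 with an estimated correlation). P4ha2 rose from 4.10 ± 0.882 to 33.0 ± 4.30 FPKM (log2 2.75, SE 0.19), and the vasodilator peptide gene Adm from 11.9 ± 1.80 to 77.4 ± 45.7 (2.46, SE 0.42). Aldoa, a glycolytic aldolase abundant in muscle, rose by 1.20 and the histone demethylase Kdm3a by 0.86. Vegfa was at 40.9 ± 26.1 FPKM, with 70.5 in sample 1 (log2 1.31, limma adjusted p = 0.0257, lost in 3 of the 9 fits that left out 1 library, highest 0.0738 without vehicle sample 3), and Hif1a at 29.6 ± 4.21 (−0.36, limma adjusted p = 0.0506). Without both libraries that lay between the groups, the HIF-1 list had a median of 0.42 (camera adjusted p = 0.0715). Of 18 glycolysis enzymes, 6 rose and 1 fell (6 and 1 adjusted over the list alone, median 0.28, camera adjusted p = 0.0424, and adjusted p = 0.688 with an estimated correlation), with Eno2 1.48 and Slc16a3 1.36 higher. That call was lost without 1 mg/kg sample 1 (median 0.10, camera adjusted p = 0.312) or 0.1 mg/kg sample 2 (0.057), and under several scalings. Of 15 heat shock and chaperone genes, 8 rose and 3 fell at 1 mg/kg (8 and 4 adjusted over the list alone, camera adjusted p = 0.0769), with Hspb1 3.52 and Bag3 1.11 higher. Leaving out vehicle sample 1 (0.0491) or 1 mg/kg sample 2 (0.0339) or 3 (0.0469) brought it past the threshold, as did removal of GC and length trends (0.0452) and fry (0.00782). At 0.1 mg/kg 3 of the 15 rose and 5 fell (4 and 5 adjusted over the list alone, camera adjusted p = 0.817).

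Further lists gave smaller or no calls. Of 8 B cell and plasma cell markers, 6 rose at 0.1 mg/kg (6 adjusted over the list alone, camera adjusted p = 0.00491, and adjusted p = 0.595 with an estimated correlation), and 3 rose and 1 fell at 1 mg/kg (the same adjusted over the list alone, 0.274). The B cell receptor component Cd79a was 2.73 and 2.47 higher. Of 14 alternatively activated macrophage genes, 7 rose at each dose (7 and 9 adjusted over the list alone, camera adjusted p = 0.00491 and 0.00293). These calls had an adjusted p = 0.595 and 0.655 with an estimated correlation. Chil3, a chitinase-like protein, rose by 3.44 at 1 mg/kg. Of 13 mitochondrially encoded mRNAs, 3 and 2 rose (2 and 2 adjusted over the list alone, camera adjusted p = 0.00712 and 0.0144, and adjusted p = 0.666 and 0.754 with an estimated correlation). The second call was lost without 1 mg/kg sample 3 (camera adjusted p = 0.0601). The list mean was 7.02, 7.93 and 8.45 in 1 mg/kg samples 1 to 3 and that of skeletal muscle markers 2.15, 4.60 and 5.92, and 0.1 mg/kg sample 3 was the highest of its group in both. At 1 mg/kg, 13 of 24 chemokines rose and 3 fell (15 and 5 adjusted over the list alone, camera adjusted p = 0.0154, and 0.0574 without 1 mg/kg sample 1). Of 14 complement genes, 6 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.0346, and 0.0823 without 1 mg/kg sample 2). With an estimated correlation these 2 lists had an adjusted p = 0.655 and 0.688.

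The lists of cholesterol synthesis, cell cycle, drug transport and MAPK feedback genes gave no camera call against vehicle at either dose. Cholesterol synthesis genes fell in 7 and 8 cases of 21 (7 and 8 adjusted over the list alone, camera adjusted p = 0.0512 and 0.0669), with the isoprenoid enzyme Idi1 1.39 and 1.27 lower in log2 units. The list passed at 0.1 mg/kg under 10 alternatives (lowest adjusted p = 0.00143, without 0.1 mg/kg sample 3) and at 1 mg/kg under 3 (0.00372, without 1 mg/kg sample 3). Of 29 cell cycle and mitosis genes, 10 and 8 fell and 4 and 5 rose (the same adjusted over the list alone, camera adjusted p = 0.229 and 0.36), including the kinesin Kif20a (log2 −1.23 and −0.96). With no filter this list passed at both doses (0.0287 and 0.0349). Of 13 drug transport and xenobiotic genes, 2 and 6 rose and 1 fell at each dose (the same adjusted over the list alone, camera adjusted p = 0.844 and 0.0504), with the glutathione transferase Gsta4 1.80 and 1.95 higher. It passed at 1 mg/kg under 12 alternatives (lowest 0.00945, without 1 mg/kg sample 2). MAPK and Src feedback genes rose in 2 and 9 cases of 18 and fell in 5 and 4 (1 and 9, then 5 and 5, adjusted over the list alone, camera adjusted p = 0.699 and 0.327). The feedback inhibitor Spred2 fell by 1.01 and 0.94.

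**Figure D3:**
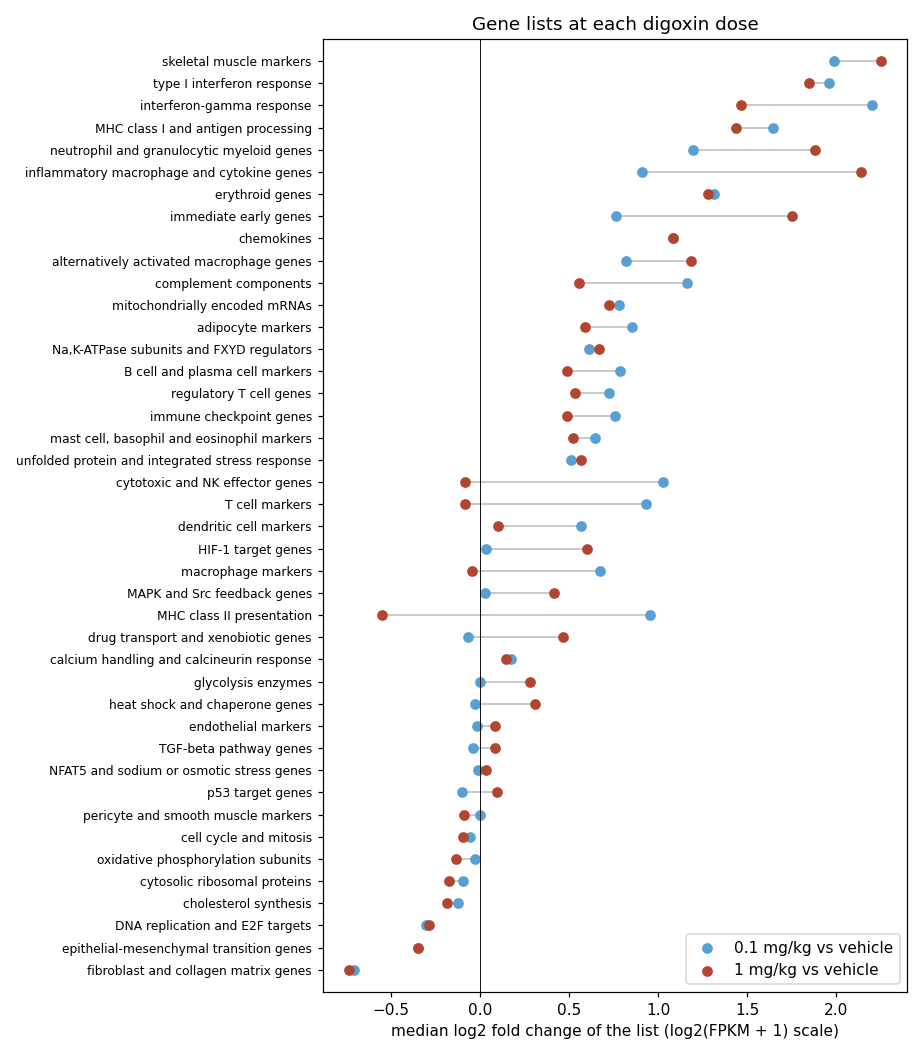
Median log2 fold change of each of the 42 tested gene lists at 0.1 mg/kg (blue) and 1 mg/kg (red), each against vehicle. Type I interferon genes sit at 1.96 and 1.85, while T cell markers sit at 0.93 and −0.09 and MHC class II genes at 0.95 and −0.55.

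The comparison of the 2 doses asked which genes differed between 1 and 0.1 mg/kg. In limma 2 of 13687 genes passed, both lower at 1 mg/kg, and 1856 genes had an unadjusted p under 0.05, against 684 expected by chance. The 684 assumes an equal spread in all groups, but vehicle libraries were more alike than most digoxin libraries. Where genes vary together, the count can also stray far from it. The excess alone therefore does not show an effect of dose, and a fit of only the 2 dose groups passed 0 genes. Gbp2b, an interferon-inducible guanylate-binding protein, was at 0.110 ± 0.0842 FPKM with vehicle, 3.79 ± 1.13 at 0.1 mg/kg and 0.129 ± 0.0891 at 1 mg/kg (log2 −2.06 between the doses, SE 0.18, limma adjusted p = 0.0179). Marcks, an actin-regulating substrate of protein kinase C, was at 23.9 ± 0.335, 30.3 ± 2.83 and 17.1 ± 0.540 FPKM (−0.79, SE 0.08, limma adjusted p = 0.0277). Gbp2b has close relatives in the guanylate-binding family, so its read assignment is uncertain. Gbp2b lost its call in 7 of the 9 fits that left out 1 library and Marcks in 8 (highest limma adjusted p = 0.167 and 0.203, without 1 mg/kg sample 3). The count of genes was 133 without 0.1 mg/kg sample 2, 1 without 0.1 mg/kg sample 3, 0 without any 1 of the other 7 libraries, and 465 (131 higher, 334 lower) without both libraries that lay between the groups.

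No gene was called higher at 1 mg/kg than at 0.1 mg/kg. The 5 with the smallest unadjusted p were Hspa1b (log2 2.29), an inducible HSP70 gene, Upk3bl (1.04), the matricellular gene Ccn2 (0.96), Il1rap (0.54) and Hsph1 (0.48), with limma adjusted p = 0.0796 to 0.0926. Among genes lower at 1 mg/kg the next values were those of Bcl2a1d (−1.20), the B cell receptor regulator Cd22 (−1.17) and the macrophage gene Ms4a7 (−1.06), each with a limma adjusted p = 0.0796. None of the targeted genes named here passed: Cd8a differed by −1.26 (limma adjusted p = 0.0953), Pdcd1 by −1.35 (0.154), Gzmb by −0.97 (0.238), Vegfa by 1.12 (0.272) and Cd274 by 0.00 (0.997).

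Camera with a preset correlation called T cell, cytotoxic, class II, macrophage and interferon-gamma lists lower at the higher dose, calls that were lost with an estimated correlation, and no single member passed over all genes. Adjusted over the list alone, 14 of 15 T cell markers fell (median log2 −0.97; camera adjusted p = 3.12e-11), with Trbc1 differing by −1.79 and Cd3d by −1.16. All 10 MHC class II genes fell (median −1.28; camera adjusted p = 6.43e-11): H2-Ab1 was at 164 ± 64.7 FPKM at 0.1 mg/kg and 32.1 ± 19.5 at 1 mg/kg, and its invariant chain partner Cd74 at 697 ± 289 and 152 ± 84.9. Of 22 interferon-gamma response genes 15 fell (median −0.67; camera adjusted p = 6.43e-11), of 12 cytotoxic and NK genes 8 fell (−0.89; 8.89e-05), and of 20 macrophage markers 10 fell (−0.55; 4.28e-07). With an estimated correlation the adjusted p = 0.271 for T cell, class II and macrophage genes, 0.369 for interferon-gamma and 0.431 for cytotoxic genes. Without 1 mg/kg sample 1 the median was −0.73 for T cell, −1.06 for class II and −0.55 for cytotoxic genes, and without 0.1 mg/kg sample 3 it was −0.49 for interferon-gamma genes. Type I interferon genes differed by a median of −0.13 (0 passed adjusted over the list alone, camera adjusted p = 0.45), and by −0.44 without 1 mg/kg sample 1 (camera adjusted p = 1.36e-11) or −0.27 without 0.1 mg/kg sample 2 (0.0122).

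The same test called hypoxia, heat shock and immediate early lists higher at the higher dose, and these calls were also lost with an estimated correlation. Adjusted over the list alone, 18 of 28 HIF-1 targets rose (median log2 0.63; camera adjusted p = 4.54e-17), with Adm differing by 2.35 and Ero1a, an endoplasmic reticulum oxidase, by 1.44. Of 23 immediate early genes 13 rose (0.90; 1.3e-17), of 18 glycolysis enzymes 5 rose (0.47; 1.34e-08), and of 18 MAPK and Src feedback genes 6 rose (0.45; 4.27e-05). The glycolysis and HIF-1 lists share genes such as Aldoa, Ldha and Pgk1, so their calls are not separate results. Of 15 heat shock genes 7 rose (0.38; 6.43e-11), including Dnajb1 (0.69). With an estimated correlation the adjusted p = 0.271 for HIF-1, immediate early and glycolysis genes, 0.369 for MAPK genes and 0.0799 for heat shock genes. All 5 medians were smallest when 1 mg/kg sample 1 was the library left out, at 0.39 for HIF-1, 0.66 for immediate early, 0.32 for glycolysis, 0.31 for MAPK and 0.30 for heat shock genes. The heat shock list was the 1 list of 42 that passed in fry, which tests whether a list's genes move one way on balance (adjusted p = 0.00956). Inflammatory cytokine genes differed by a median of 0.74 (1 rose adjusted over the list alone, camera adjusted p = 6.18e-08, and adjusted p = 0.369 with an estimated correlation), and by 0.18 without both libraries that lay between the groups (0.0778). Neutrophil genes differed by 0.66 (0 passed adjusted over the list alone, camera adjusted p = 5.3e-05, and adjusted p = 0.489 with an estimated correlation), and by 0.37 without 0.1 mg/kg sample 3. Skeletal muscle markers differed by 0.24 (camera adjusted p = 0.208), and by 1.27 without 1 mg/kg sample 1 (8.2e-07).

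Other camera calls between the doses rested on small medians or single libraries. Of these lists, class I genes differed by a median log2 of −0.25 (1 fell adjusted over the list alone, camera adjusted p = 0.00551), lost without 0.1 mg/kg sample 1 (0.112) or 3 (0.53) or 1 mg/kg sample 3 (0.0567). B cell markers differed by −0.92 (3 fell adjusted over the list alone, camera adjusted p = 0.00585, and 0.0906 without 1 mg/kg sample 1). Complement genes differed by −0.60 (2 fell adjusted over the list alone, camera adjusted p = 0.0124, and 0.112 without 0.1 mg/kg sample 1). Oxidative phosphorylation subunits differed by −0.16 (0 passed adjusted over the list alone, camera adjusted p = 0.00253, and 0.0847 without 0.1 mg/kg sample 2). Stress response genes differed by 0.15 (1 rose adjusted over the list alone, camera adjusted p = 4.03e-05, and 0.251 without 0.1 mg/kg sample 2), and p53 target genes by 0.10 (2 rose adjusted over the list alone, camera adjusted p = 0.00585, and 0.231 without 1 mg/kg sample 1). NFAT5 and osmotic genes differed by 0.06 (2 rose adjusted over the list alone, camera adjusted p = 0.00359, and 0.0515 without both libraries that lay between the groups) and drug transport genes by 0.24 (3 rose adjusted over the list alone, camera adjusted p = 5.58e-05). Without 1 mg/kg sample 1 these medians were 0.03 and 0.15. TGF-beta genes differed by 0.01 (4 rose adjusted over the list alone, camera adjusted p = 0.0484, and 0.301 without 1 mg/kg sample 1, 0.243 without 0.1 mg/kg sample 3 and 0.0795 without vehicle sample 1). With an estimated correlation the adjusted p = 0.702, 0.369, 0.489, 0.618, 0.431, 0.369, 0.271, 0.271 and 0.403 in the order given.

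The fold changes of the 2 doses against the shared vehicle libraries correlated across the 13687 genes, which are not independent replicates, with Pearson r = 0.919 and Spearman rho = 0.905. Unchanged groups simulated against the same vehicle libraries gave a median r of 0.589 (95% of 100 draws between −0.171 and 0.903). The covariance was 0.431 against a simulated median of 0.0194 (upper limit of 95% of the draws 0.0877), a difference of 0.411. Both doses called 2181 genes higher and 2463 lower, where independent lists of the same lengths would share 611 and 712, and 1 gene was called in opposite directions. The 3 vehicle libraries could not be split into 2 sets of at least 2, so part of the excess in r and in shared calls may come from the shared controls.

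**Figure D4:**
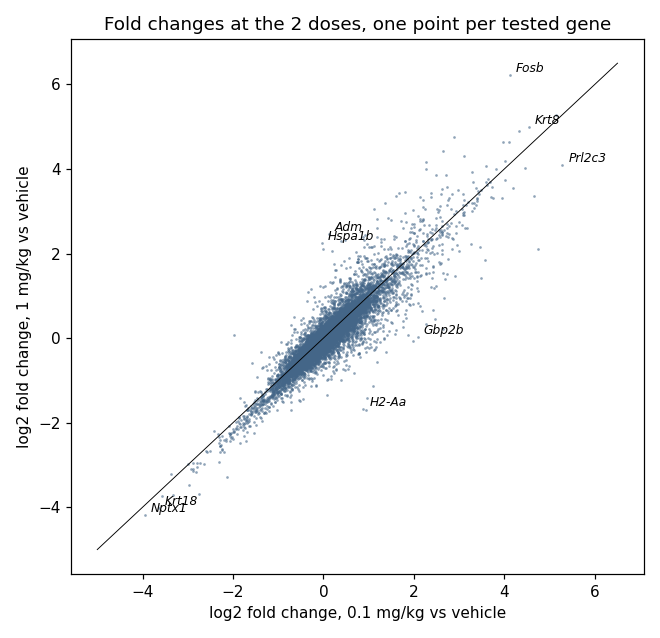
Log2 fold change of each of the 13687 tested genes at 1 mg/kg (vertical) against 0.1 mg/kg (horizontal), both against the same vehicle libraries, with the line of equal change. The points follow the line (r = 0.919); Fosb (4.12 and 6.23) lies above it and Gbp2b below.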

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

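Of the tests in this part, the thinning of all libraries to 1 depth was specified before its result was seen, and the splits of the samples and the GC and length, cell type, chromosome, mixing and muscle tests were chosen after the result was seen. Gbp2b and Marcks drew attention because their effects at the 2 doses differed in a limma test of the difference itself. Gbp2b differed by −2.06 on the log2 scale (limma adjusted p = 0.0179, 0.00346 to 0.329 over the alternatives) and Marcks by −0.79 (0.0277, 0.00557 to 0.409). All 3 samples of the 1 mg/kg group lay below all 3 of the 0.1 mg/kg group for both genes. Both were picked by a test on these same values, so this adds no support. Over all tested genes the values did not overlap between the doses for 17%, against 10% by chance. Gbp2b lost its call in 7 and Marcks in 8 of the 9 fits that left out 1 library, most strongly without 1 mg/kg sample 3 (0.167 and 0.203).

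With 10 splits of 6 samples, no share under 0.05 can be reached. For 0.1 mg/kg against vehicle 1 of the 10 splits, the real one, gave as many as 5781 genes, and the highest other gave 3. For 1 mg/kg against vehicle the real split gave 6277 and the highest other 0, so that again 1 of 10 was as large. Between the doses 2 of the 10 splits gave at least 2 genes, the highest other giving 6. With both doses together, a model of 2 groups gave 6702 genes in the real split and at most 6 in any other of the 84 splits. Only 1 of 84 was as large, so a division by luck is unlikely there if the samples are independent. The labels do not state that they are, so luck in which tumours fell into which group was not excluded.

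The first pattern was that vehicle and digoxin libraries differed in 7016 genes. After all libraries were thinned to the shallowest depth, 98.6% of the calls for both doses together were kept in the same direction, and with GC and length trends removed 88.8% were kept, which argues against either as the whole cause. A lower share of tumour cells alone would raise markers of every other cell type alike, but the neutrophil median exceeded the endothelial median by 1.38 (95% interval 1.00 to 2.30). That interval came from resampling the genes of each list, so it holds no spread between samples. A lower share together with a change among the other cell types would also give unequal medians, so it stays open. Tumour cells of another genetic make-up could not be told apart from a treatment effect: chromosome medians varied 4.79 times as much as in random reassignments of genes, within the ratio of up to 5.55 that single vehicle libraries reached, a bar set after the vehicle values were seen. The SD of those medians was 0.127 for digoxin against vehicle and 0.0256 to 0.0332 for single vehicle libraries. Each ratio divides by the SD of its own random reassignments, 0.0266 for digoxin and 0.00582 to 0.00761 for vehicle libraries. A contrast with little spread can thus reach a high ratio, so the ratio of the vehicle libraries is a poor bar for the shift with digoxin. A response to digoxin, which the design names, or a difference between tumours that existed before treatment may account for the pattern. Which of them is likelier was not tested.

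The second pattern was that 0.1 mg/kg sample 2 and 1 mg/kg sample 1 lay between the groups. Genes high with vehicle and low in the other samples of the group stood at a median of 54.6% of the vehicle level in the first library (75 genes) and 26.4% in the second (85 genes). If vehicle-type material had been mixed in at 1 share, these genes would give 1 value, but the 10th to 90th percentile range was 125% of the median share in the first (vehicle libraries 27.2% to 40.0%) and 133.3% in the second (29.5% to 42.2%). This relative scale was chosen after the range in percentage points had been seen, which was 68.3 against 27.3 to 38.7 in the first library and 35.2 against 29.5 to 38.1 in the second, so that on that scale the second library gave no evidence against mixing, which stays open there. Gene by gene the shares in both libraries correlated when each was taken against different vehicle libraries (Spearman rho = 0.849 to 0.895 over 65 to 71 genes, which are not independent replicates), and vehicle-type cells with a profile of their own or a weaker response of the same genes may each give this, so both stay open.

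The third pattern was that skeletal muscle genes differed between libraries. The list mean on the log2 scale was 2.45, 1.58 and 1.60 with vehicle, 4.31, 3.33 and 4.39 at 0.1 mg/kg and 2.15, 4.60 and 5.92 at 1 mg/kg. Over the 9 libraries 94.3% of the variance of the list lay on 1 component, against at most 79.8% (median 55.5%) in 1000 random lists of genes with similar mean expression. The abundant muscle actin Acta1 was at 62.1, 21.0 and 19.5 FPKM with vehicle, 116, 76.4 and 140 at 0.1 mg/kg and 23.9, 140 and 420 at 1 mg/kg. In this list 14 of the 20 genes were tested and 1 of the 20 (Ryr1) is in another list. Muscle tissue taken along with some tumours is a candidate source, and a change of muscle around the tumours under digoxin stays open. Muscle genes would vary together under either, so the comparison with random lists cannot tell them apart.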

How the results depend on the processing

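The settings without both libraries that lay between the groups, limma-voom, the GC and length correction and the count for both doses were chosen after the results were seen, and the remaining alternatives before. The cause of a change was not tested unless given. Against vehicle, 5781 genes passed at 0.1 mg/kg, 6277 at 1 mg/kg and 7016 for both doses. These counts stayed within 1.5 times under the other pseudocounts, no filter, all scalings and both variance models. They did so too under limma-voom (5992, 6304, 7091) and the GC and length correction (5630, 6313, 7009). The fit of only 2 groups, run for each dose alone, also kept the counts of the single doses within 1.5 times. With a mean of at least 5 FPKM, 4159 genes passed at 1 mg/kg, 4550 for both doses and 1 between the doses, because only 8179 genes were tested. Requiring a 2-fold change left 1222, 1369 and 1311 genes and 1 between the doses, and an unadjusted p with a 2-fold change gave 1299, 1437, 1354 and 137. Leaving out 1 library gave 3414 to 7074 genes at 0.1 mg/kg, 4129 to 7373 at 1 mg/kg, 4770 to 8178 for both doses and 0 to 133 between the doses, the 133 (11 higher, 122 lower) without 0.1 mg/kg sample 2. Without both libraries that lay between the groups the counts were 8424, 8392, 9154 and 465, and 99.5% of the calls for both doses were kept.

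Between the doses, limma gave 0 genes with a pseudocount of 0.1 or 0.01 or with only the 2 groups fitted, 1 with equal medians or without trend, and 10 (4 higher, 6 lower) with no filter. Under the chosen settings 1856 genes had an unadjusted p under 0.05 there, and limma-voom gave 2. For both doses, rescaling to TPM turned the split of 3383 higher and 3633 lower genes into 2818 and 4589, and the median log2 change of all genes was then −0.12 at 1 mg/kg and −0.10 for both doses. Camera called 20, 16, 21 and 16 lists at 0.1 mg/kg, 1 mg/kg, between the doses and for both doses, and 0, 0, 0 and 0 with an estimated correlation. It called 25 of 45 lists at 1 mg/kg with no filter, against 16 of 42. There, 9 of the 42 lists gained a call and 0 lost one. The background was then all 35321 genes, most of them below the expression filter, so these gains are not like for like. Fry, which does not compare a list with other genes, called 23, 16, 1 and 22 lists in the same order of comparisons. The list of the unfolded protein and integrated stress response turned from 0.15 to −0.0197 between the doses without both libraries that lay between the groups. Leaving out 1 library kept 1591 of 1746 results for named genes at 0.1 mg/kg and 1561 of 1701 at 1 mg/kg with the same call. Between the doses it kept 1534 of 1575, but nearly all of these were genes without a call. The called genes Gbp2b and Marcks lost their call in 15 results there. In all 3 comparisons 0 were reversed. The correlation between the doses was 0.887 to 0.945.

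Replicate numbers were checked as a pairing of the samples. Deviations of same-numbered samples correlated at 0.193, 0.132 and 0.091 between vehicle and 0.1 mg/kg. The values were 0.001, −0.059 and −0.006 between vehicle and 1 mg/kg, and −0.244, −0.441 and 0.279 between the doses. Differently numbered samples gave −0.135 to 0.036, −0.099 to 0.146 and −0.475 to 0.52 in that order. Same-numbered samples were thus more alike only between vehicle and 0.1 mg/kg, and 3 samples per group cannot settle whether the numbers mark pairs. The replicate block gave 4967, 5541, 0 and 6465 genes. Depth limited the lowest values, where 1 read was worth up to 1.20 times as much FPKM as in vehicle sample 1.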

Other observations

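The pathway sets, Peg10 and the values per library in this part were chosen after the results were seen. Pathway annotations deposited with the table gave further groups. At 0.1 mg/kg, 52 of the nucleocytoplasmic transport genes fell and 8 rose (camera adjusted p = 7.37e-05), with 31 of 73 ribosome biogenesis genes falling and 4 rising (0.00222), 46 of 127 spliceosome genes falling and 12 rising (0.00691), and 14 of 28 citrate cycle genes falling and 2 rising (0.00335). At 1 mg/kg the same sets fell in 48, 32, 50 and 19 cases and rose in 7, 3, 15 and 2 (camera adjusted p = 0.0124, 0.0124, 0.0452 and 0.0124). Terpenoid backbone genes, which feed cholesterol synthesis, fell in 10 and 12 cases of 20 and rose in 0 (0.00936 and 0.0147). These calls had an adjusted p = 0.742 at 0.1 mg/kg and 0.901 at 1 mg/kg with an estimated correlation. Circadian rhythm genes rose in 13 cases of 27 and fell in 3 at 1 mg/kg (camera adjusted p = 0.0311, and adjusted p = 0.901 with an estimated correlation), and sampling times are not used here.

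Peg10 was at 7.74, 14.4 and 12.0 FPKM in vehicle samples 1 to 3, 0.189, 8.81 and 0.246 at 0.1 mg/kg and 5.29, 0.281 and 0.270 at 1 mg/kg. Nptx1 followed with 44.0, 59.1 and 57.3, then 0.608, 15.7 and 0.611, then 8.95, 0.472 and 0.804 FPKM. For both genes the high digoxin values were those of the libraries that lay between the groups. Krt8 did not share this course in 1 mg/kg sample 1, where it was at 116 FPKM, near its group mean. In 0.1 mg/kg sample 2 it was at 58.7, below its group mean but far above the 1.70 to 4.13 with vehicle.

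Lists without a camera call against vehicle are given as values, at 0.1 and 1 mg/kg. Camera adjusted p were 0.0951 and 0.17 for regulatory T cell genes, 0.122 and 0.456 for dendritic cell markers, 0.252 and 0.169 for mast cell, basophil and eosinophil markers, 0.993 and 0.274 for p53 target genes, and 0.844 and 0.133 for oxidative phosphorylation subunits. They were 0.196 and 0.137 for ribosomal proteins, 0.382 and 0.771 for epithelial-mesenchymal transition genes, 0.597 and 0.771 for TGF-beta genes, 0.702 and 0.66 for pericyte markers, 0.0704 and 0.169 for adipocyte markers, 0.175 and 0.209 for erythroid genes, and 0.417 and 0.274 for calcium handling genes. Some of them passed under other settings. At 0.1 mg/kg these were the lists of regulatory T cell genes (no filter, TPM and fry, lowest adjusted p = 0.000673), dendritic cells (fry, 0.0142), mast cells (without both libraries that lay between the groups, 0.0484), ribosomal proteins (4 settings, lowest 0.00339), adipocytes (9 settings, lowest 0.0027) and calcium handling (fry, 0.0363). At 1 mg/kg they were regulatory T cell genes (no filter, 0.0349), mast cells (2 settings, lowest 0.00358), oxidative phosphorylation (4 settings, lowest 0.00353), ribosomal proteins (7 settings, lowest 0.00233) and adipocytes (2 settings, lowest 0.0389). The lists of p53, epithelial-mesenchymal transition, TGF-beta, pericyte and erythroid genes passed under 0 settings. Lists of keratinocyte, neural and Th17 genes had under 5 tested members and were tested only with no filter.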
